A study of Mus musculus with 76 samples.

How the data were processed

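Hearts of 38 C57BL/6 mice kept on a regular diet with free access to food were measured, per the labels, and every mouse gave 1 sample on each of 2 membrane array types, A and B. Per the labels' protocols, total RNA was purified on spin columns from tissue broken up with glass beads, copied into cDNA carrying radioactive phosphorus, and hybridised. Each membrane type holds 8448 spotted cDNA clones. The deposited values are z-scores, a score computed by the authors within each array: every array has a mean of 0 and an SD of 1.00 over its spots. The scale before the z-score, the background correction and any filter are not given in the sources used here. Differences are therefore in SD units of the array, no fold can be stated, and a z-score places a clone only relative to the other clones of its membrane. The 76 columns were used as deposited and 0 other columns of samples were present.

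Clones were named through the platform annotation. Of 16896 clones, 9663 had 1 gene symbol, 436 had several and were not named, and 6797 are unnamed here. The named clones cover 7151 genes. No genome coordinates were used. No pair of arrays was identical among the 703 pairs of each type, and the median correlation between arrays was 0.9544 on type A and 0.9707 on type B. The number of arrays limits the precision, and the labels describe each mouse as a separate animal.

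Age and sex came from the labels. Ages fall into 5 bands: 17-19 days, 33-44 days, 169-194 days, 476-499 days and 704-743 days. The mouse numbers in the labels fall into 5 runs, called number sets here, of 8, 7, 7, 8 and 8 mice, each passing from young to old animals. The labels do not say that these runs are batches or that the numbers follow the order of processing. If they do, drift along a run cannot be told apart from age among adults, because every run orders the adult bands by age. The number-set block, splits within sets and agreement across sets do not remove such drift. Values with the number set as a block and differences within each set are given because the arrays differed between runs: at equal age band and sex, 7634 clones (45.2%) differed between set 2 and set 1, 48 between set 3 and set 2, 0 between set 4 and set 3 and 0 between set 5 and set 4.

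Tests used R 4.3.3 with limma 3.58.1 (lmFit and eBayes) per array type, with the P values of both types pooled for 1 Benjamini-Hochberg adjustment at 0.05. The 8 comparisons were the age slope over all mice and over adults of at least 169 days, 4 contrasts of age bands, male against female, and the age by sex interaction. Slopes are per 100 days. All tests were two-sided unless stated. Gene lists were tested with camera at a preset correlation of 0.01, on the brightest clone of each gene, adjusted over the 27 of 30 lists that had at least 3 measured genes. Estimated correlation and fry were alternatives.

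The designs, 30 lists, the naming rule and most alternatives were fixed before the data were examined. The rule names genes that pass, and where none passes the 3 smallest P values in each direction, plus up to 2 rising and 2 falling members of each list, plus the sex-linked genes in the sex comparison. To keep the text short, members are named here from at most the 6 lists with the smallest camera P and only at an unadjusted P under 0.05. That restriction was set after values had been seen, first at 3 lists and then at 6, so the members named lean towards the larger changes. Members of the sarcomere and fetal heart lists, red cell genes and clones called without number set 1 are named outside the rule and were chosen after their values were seen.

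Alternatives per comparison numbered 22 to 32, apart from leaving out each of the 38 mice in turn. Of these, 11 to 15 were added after the data had been seen. The added ones leave out number set 1, leave out mice 05, 09 and 64 or mice 05, 06 and 09, combine leaving out set 1 with the block or with log10 of age, combine cyclic loess with log10 of age, or correct for spot position. Mice 09 and 05 had the lowest median correlation with the other arrays on both types (0.8656 and 0.8706 on A). On B the lowest after them was mouse 64 (0.9345), but on A, where mouse 64 had 0.9553, many other mice were below it, and over the mean of both types the lowest after them was mouse 06. The spot layout is not given in the sources used here. It was inferred from the values as 22 interleaved blocks of 16 rows by 24 columns, because spots next to each other in that layout moved together across mice. The mean residual correlation was 0.622 (A) and 0.589 (B) between neighbouring columns, against a median of 0.0323 and 0.0514 between spots of different blocks. A shift shared by a whole block would give that contrast too, so it does not by itself fix the rows and columns or show a fall with distance. The correction subtracted, per mouse and spot, the median deviation of the surrounding window. Windows of 3 by 3, 5 by 5 and 7 by 7 were all tried, and the middle size is the one quoted unless another is named. With that size the residual correlation between neighbouring columns was still 0.208 (A) and 0.211 (B). The median between spots of different blocks was 0.0108 and 0.0282, so shared movement of neighbouring spots was reduced but not removed. The correction also removes any real change shared by neighbouring clones.

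The fits were tested on simulated data with 200 of 16896 clones changed. At a change of 0.4 SD units, 81.5% of changed clones were recovered for the age slope over all mice, 46% for the adult slope, 38% for 33-44 against 17-19 days, 58.5% for 169-194 against 33-44 days, 80.5% for 476-499 against 169-194 days, 75% for 704-743 against 169-194 days, 91.5% for sex and 11% for the interaction. At 0.2 SD units, nearer to many of the differences named, recovery in the same order was 11%, 0%, 0%, 0.5%, 7.5%, 12.5%, 41.5% and 0%, so 0 calls say little about changes of that size. For the slopes and the interaction the size put in was the change from 17 to 743 days. The adults spanned only part of it, so their recovery is for a smaller change within adult life. The simulated clones varied independently, so these shares leave out the shared drift of neighbouring spots. They also take each clone to measure its gene, which the sex-linked clones below leave open. The floor alternative was not applicable to z-scores.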

Results

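Gene expression was measured in the hearts of 38 mice, 19 males and 19 females aged 17 to 743 days, to compare animals by age and sex. The 17-19 day band held 4 mice, the 33-44 day band 5, the 169-194 day band 10, the 476-499 day band 10 and the 704-743 day band 9. Each mouse had 1 array of each of 2 membrane types carrying cDNA clones, and values are z-scores within an array.

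Over the whole age range the clearest single trend belonged to Dazap1, an RNA-binding protein gene, whose slope was 0.0375 ± 0.00724 z-score units per 100 days (SE, n = 38; adjusted p = 0.111). Its mean was 0.138 ± 0.0818 (SD, n = 4) at 17-19 days and 0.451 ± 0.0762 (SD, n = 9) at 704-743 days, and the slope was upward in both sexes. Cog2, a subunit of the Golgi tethering complex, and Vps4a, an ATPase of the endosomal sorting machinery, had slopes of 0.0416 ± 0.0105 and 0.0342 ± 0.0088 (SE; adjusted p = 0.552 for each). Negative slopes were led by Slc25a17, a peroxisomal carrier (-0.0227 ± 0.00584, SE), Adamtsl1, a secreted matrix protein (-0.0427 ± 0.0113, SE), and Xpr1, a phosphate exporter (-0.0285 ± 0.0076, SE), each at adjusted p = 0.552. Corrected for spot position, these slopes were 0.0276 for Dazap1, 0.0174 for Cog2, 0.0182 for Vps4a, -0.0037 for Slc25a17, -0.0253 for Adamtsl1 and -0.00484 for Xpr1. No clone passed: limma called 0 of 16896, and the plain linear model also called 0. At an unadjusted P under 0.05 there were 1243 clones, where 844.8 would be chance if clones varied independently. Clones moved together here, and other splits of the mice gave a median of 508 and up to 4612, so this is no clear excess. In each of the other comparisons the limma count lay below 844.8. With the number set as a block 2 clones passed, and without number set 1, 56 passed, 54 of them upward. Dazap1 passed in 10 of 70 alternatives, among them array weights, number sets as a random block and the mean of clones. Under the mean of clones its only clone kept the slope of 0.0375, but 7151 genes were adjusted in place of 16896 clones. The remaining passes left out number set 1, a setting chosen after the data were seen, or 1 mouse. Without number set 1 Dazap1, Vps4a and Cog2 passed (limma adjusted p = 0.0483, 0.0216 and 0.0459). None of them did with the position corrected as well (0.0841, 0.213 and 0.402).

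Of 62 measured genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 47 had negative slopes with age. The median slope was -0.00973 per 100 days, and the list passed camera (adjusted p = 0.00347) while 0 members passed singly, over all clones or adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.762), with fry (adjusted p = 0.427) and without number set 1 (adjusted p = 0.914), and without set 1 with the number-set block the direction turned (adjusted p = 0.97). The list passed in males alone (adjusted p = 0.00424) and not in females alone (adjusted p = 0.115), and it was lost without mouse 01 (0.0847) or mouse 14 (0.0619). As many lists were called in 33 of 100 splits of the mice, the real one included. Examples are Ndufv1 of complex I (-0.0134 ± 0.0055, SE) and Atp5b of ATP synthase (-0.0224 ± 0.00923, SE), while Atp5g3, also of ATP synthase, went the other way (0.0252 ± 0.00923, SE). In the citric acid cycle 17 of 22 genes had negative slopes (adjusted p = 0.121), among them Got2 (-0.0424 ± 0.0142, SE) and Idh2 (-0.0294 ± 0.0128, SE). In glycolysis 13 of 21 did (adjusted p = 0.159), with Pkm, pyruvate kinase, at -0.0291 ± 0.0117 and the glucose transporter gene Slc2a4 at -0.0277 ± 0.0121 (SE). Of 67 cytosolic ribosomal protein genes 42 had negative slopes (adjusted p = 0.121), with Rpl23 at -0.0285 ± 0.00831 and Rpl38 at -0.0221 ± 0.00819 against Rpl37 at 0.0178 ± 0.00584 and Rps4x at 0.0264 ± 0.0114 (SE). After the position correction the slopes were 0.00173 for Atp5g3, -0.00396 for Atp5b, -0.0137 for Idh2, -0.0194 for Pkm, -0.0146 for Slc2a4, 0.00475 for Rpl37 and -0.00148 for Rpl38, and the sign of Rps4x turned. The other clone of Got2 went the other way, and without number set 1 its slope was -0.0221 (unadjusted P = 0.127), that of Slc2a4 -0.017 (0.144) and that of Rpl38 -0.0104 (0.208). Among markers of other cell types, 7 of 8 endothelial genes had negative slopes (adjusted p = 0.476), led by Nos3, endothelial nitric oxide synthase, at -0.0407 ± 0.0159 (SE). The Nos3 clone is dim, at percentile 2.34 of brightness.

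**Figure D1:**
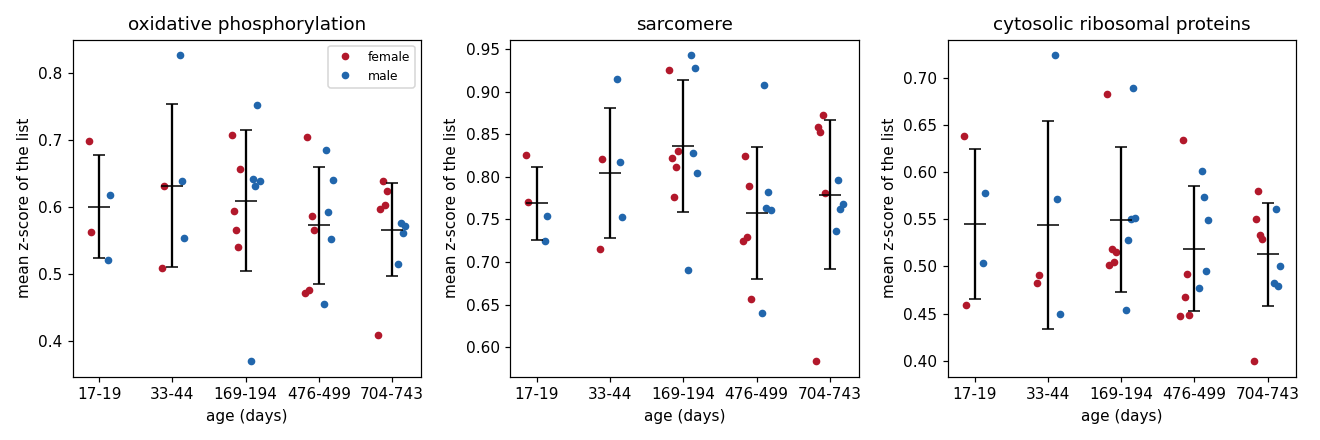
Mean z-score of the measured members of 3 gene lists (vertical axis) in each mouse, by age band in days (horizontal axis). Points are single mice, female in red and male in blue, and bars give mean and SD. The oxidative phosphorylation mean is 0.61 ± 0.105 at 169-194 days and 0.573 ± 0.0874 at 476-499 days, and the bands overlap in every panel.

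Restricting the slope to the 29 adults asked for change in adult life alone. Fkbp4, a co-chaperone of Hsp90, had the smallest P, with a slope of -0.0394 ± 0.00945 per 100 days (SE, n = 29; adjusted p = 1), a mean of -0.572 ± 0.0769 (SD, n = 10) at 169-194 days and -0.78 ± 0.117 (SD, n = 9) at 704-743 days, and its other 2 clones went the same way. Rpl23 (-0.0393 ± 0.0107, SE) and Xpr1 (-0.0398 ± 0.0108, SE) followed. Positive slopes were led by Adamts12, a secreted metalloprotease of the ADAMTS family (0.0578 ± 0.017, SE), Dazap1 (0.0294 ± 0.00887, SE) and Serinc5 (0.0416 ± 0.0128, SE). The Adamts12 clone is dim, at percentile 4.42. Serinc5 was at 0.0043 and Xpr1 at -0.0107 after the position correction. Limma called 0 clones, with 486 at an unadjusted P under 0.05, and the plain linear model called 0.

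Oxidative phosphorylation was the only list of 27 to pass in adults (adjusted p = 0.0232), with 45 of 62 members lower and a median slope of -0.00961 per 100 days. It was lost with an estimated correlation (adjusted p = 0.641), fry (adjusted p = 0.511) and the number-set block (adjusted p = 0.116), in females alone (adjusted p = 0.362) and without number set 1 (adjusted p = 0.147). Leaving out 1 mouse lost it for any of 7 mice, with adjusted p up to 0.388 (mouse 45). As many lists were called in 34 of 100 splits of the mice. In glycolysis 16 of 21 genes were lower (adjusted p = 0.0514), with Pkm at -0.0493 ± 0.0154 and Tpi1, triosephosphate isomerase, at -0.0391 ± 0.0148 (SE; -0.0221 after the position correction). Of 9 sarcomere genes 8 were lower (adjusted p = 0.0514), including Cryab, a small heat shock protein, at -0.0177 ± 0.00849 (SE; -0.00954 after the position correction). Ribosomal protein genes were lower in 44 of 67 (adjusted p = 0.0514), and Rps27l, a dim clone at percentile 6.87, stood at -0.0306 ± 0.0119 (SE). The dim Nos3 clone had a slope of -0.062 ± 0.0236 (SE), with 6 of 8 endothelial genes lower (adjusted p = 0.268).

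Between 17-19 and 33-44 days, on either side of weaning, Map3k2, a kinase of the MAP kinase cascade, was higher at 33-44 days by 0.436 ± 0.111 (SE), as were Ubac1 (0.354 ± 0.089, SE) and Hpn, a serine protease (0.316 ± 0.0813, SE). Tmem131 (-0.283 ± 0.0696, SE), Ccdc14 (-0.248 ± 0.0695, SE) and Dkc1, the pseudouridine synthase of small nucleolar RNPs (-0.312 ± 0.0875, SE), were lower. These 6 had adjusted p = 0.899 and the same direction in each of the 3 number sets holding both bands. Each of those sets held only 1 mouse of each band, of opposite sex. As these genes were picked by their P, their agreement across sets is not separate support. Corrected for spot position, they were at 0.217, 0.149, 0.0913, -0.136, -0.132 and -0.0608, in the order named. The Ubac1 clone is dim, at percentile 7.62, and the other clone of Dkc1 went the other way. Limma called 0 clones, with 756 at an unadjusted P under 0.05. The plain linear model called 0, and array weights called 9, Tmem131 among them.

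No list passed in this comparison, though 2 did with all clones of each gene. Of 25 fatty acid oxidation genes 17 were higher at 33-44 days (median 0.0655; adjusted p = 0.803), with Acot2, a mitochondrial acyl-CoA thioesterase, at 0.4 ± 0.136 (SE). Got2 was lower by -0.402 ± 0.145 (SE), though its other clone differed in sign. Among matrix genes Nid1, a basement membrane protein, was at 0.225 ± 0.096, while Serpinh1, the collagen chaperone, was at -0.199 ± 0.0777 and Emilin1 at -0.199 ± 0.0839 (SE). After the position correction these 3 were at 0.0519, -0.0261 and -0.0255, and Acot2 was at 0.0657. The other clone of Nid1 went the other way. Among red cell markers, which passed in no comparison (adjusted p = 0.803 here), the 16 alpha-globin clones, singled out after their values were seen, were lower at 33-44 days by a median of -0.469 (smallest adjusted p = 0.901), while the other 6 red cell genes had a median of -0.000758.

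**Figure D2:**
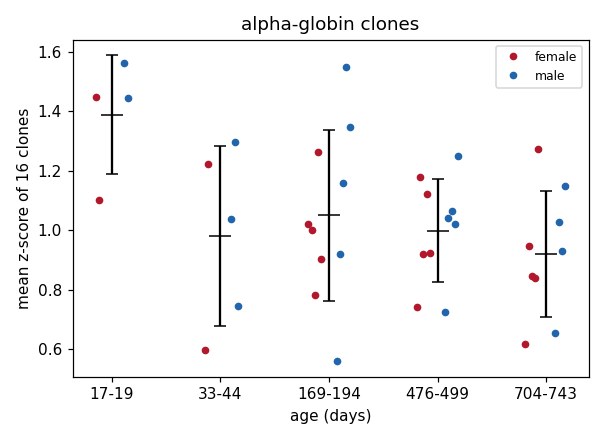
Mean z-score of the 16 alpha-globin clones (vertical axis) in each mouse, by age band in days (horizontal axis). Points are single mice, female in red and male in blue, bars give mean and SD, and the mean is 1.39 ± 0.201 at 17-19 days and 0.981 ± 0.302 at 33-44 days, with overlapping values.

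Between 33-44 and 169-194 days the genes with the smallest P were Crbn (0.229 ± 0.0787, SE), the chromatin remodeller gene Chd8 (0.384 ± 0.136, SE) and Ppip5k1 (0.163 ± 0.0615, SE), all higher at 169-194 days, and 6230400D17Rik (-0.51 ± 0.151, SE), Eif2s3x (-0.176 ± 0.063, SE) and the cap-binding gene Ncbp1 (-0.198 ± 0.0762, SE), all lower. Each had adjusted p = 1. The clones of Chd8 and 6230400D17Rik are dim, at percentiles 2.23 and 1.17, and 1 of the other 2 clones of Chd8 went the other way. Ncbp1 was at -0.0999 after the position correction, and Ppip5k1 at 0.0875 without number set 1. Limma called 0 clones, with only 69 at an unadjusted P under 0.05, and the plain linear model called 0. No list passed. Of 9 sarcomere genes 6 were higher at 169-194 days (median 0.049; adjusted p = 0.206), with Cryab at 0.13 ± 0.0555 (SE). Eif2s3x alone passed when adjusted over its own list of X-linked genes that escape inactivation. Without number set 1, 3 lists passed, the sarcomere among them (adjusted p = 0.0378), and after the position correction 1 list did.

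At 476-499 days, sarcomere genes lay below their 169-194 day level in 9 of 9 members (median -0.087), and the list passed camera (adjusted p = 0.00213) but not with an estimated correlation (0.109) or fry (0.144). The list mean was 0.836 ± 0.0777 (SD, n = 10) at 169-194 days and 0.758 ± 0.0778 (SD, n = 10) at 476-499 days, and was lower in 5 of 5 number sets. Members include Cryab (-0.097 ± 0.0453, SE), the Z-disc protein gene Actn2 (-0.083 ± 0.0413, SE), Tpm1, tropomyosin (-0.094 ± 0.0795, SE), and Nexn (-0.087 ± 0.056, SE). The others measured were Fhl2, Vcl, Pdlim1, Pdlim5 and Flnc, and no myosin, troponin or titin gene of the list was measured. Vcl was near no change (-0.01 ± 0.103, SE). After the position correction Vcl was at 0.00543 and Flnc at -0.00264. Oxidative phosphorylation also passed (adjusted p = 0.00405), with 46 of 62 genes lower, a median of -0.0465, and Ndufa12 at -0.147 ± 0.0596 and Atp5b at -0.145 ± 0.068 (SE; -0.0787 after the position correction). Its list mean was lower in 4 of 5 number sets. The citric acid cycle (16 of 22 genes lower) and glycolysis (13 of 21, with Pkm at -0.213 ± 0.0811, SE) each passed at adjusted p = 0.0471. The list mean was lower in 5 of 5 number sets for the citric acid cycle and in 4 of 5 for glycolysis. All of these lists, the sarcomere included, were called on the same mice, so agreement across sets is not separate support. With an estimated correlation oxidative phosphorylation (adjusted p = 0.609), the citric acid cycle (0.558) and glycolysis (0.558) did not pass either, nor did any of them with fry. Leaving out 1 mouse in turn lost the citric acid cycle in 16 of 38 fits, glycolysis in 17, oxidative phosphorylation in 4 and the sarcomere in 0. With the number-set block the citric acid cycle and glycolysis were lost (adjusted p = 0.0523 for each). As many lists were called in 7 of 100 splits of these mice, the real one included. With the block, the 2 lists that stayed were matched in number in 31 of 100 splits within number sets.

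Single genes did not pass in this comparison. Wdr75 (0.239 ± 0.0768, SE), the centrosomal gene Cep57 (0.28 ± 0.0907, SE) and Thsd7a (0.26 ± 0.0961, SE) were higher at 476-499 days, and Vps13d (-0.144 ± 0.0429, SE), Upf2, of nonsense-mediated decay (-0.177 ± 0.0553, SE), and Tcirg1, of the vacuolar ATPase (-0.148 ± 0.0485, SE), were lower, each at adjusted p = 0.999. The clones of Wdr75 and Cep57 are dim, at percentiles 5.73 and 1.84, and the other clone of Vps13d went the other way. After the position correction Thsd7a was at 0.0944, Vps13d at -0.0669, Upf2 at -0.0734 and Tcirg1 at -0.0678, and without number set 1 Thsd7a was at 0.144. The limma count was 0 clones, with 278 at an unadjusted P under 0.05, and the plain linear model called 0. Ribosomal protein genes were lower in 41 of 67 (adjusted p = 0.0583), with Rpl23 at -0.152 ± 0.0607 and Rps24 at -0.152 ± 0.0694 (SE; -0.0613 after the position correction), while 1 of the other 2 clones of Rpl23 went the other way. Tpm2, of the fetal heart programme, was at -0.148 ± 0.0599 (SE), in a list with 6 of 8 members lower (adjusted p = 0.0583).

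The oldest mice, 704-743 days, were compared with the same 169-194 day mice, so both contrasts share those animals. Fkbp4 was lower by -0.21 ± 0.0517, Xpr1 by -0.213 ± 0.054 and Yipf5 by -0.158 ± 0.044 (SE), in 5 of 5 number sets each. Being picked by their P, these genes gain no separate support from that agreement. Adamts12 (0.314 ± 0.095, SE), Serinc5 (0.219 ± 0.0712, SE) and the DNA polymerase gene Poll (0.24 ± 0.082, SE) were higher. Each had adjusted p = 1. Serinc5 was at 0.0189, Poll at 0.054, Xpr1 at -0.052 and Yipf5 at -0.0572 after the position correction. Limma called 0 clones, with 427 at an unadjusted P under 0.05, and the plain linear model called 0.

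No list passed at 704-743 days. Oxidative phosphorylation was lower in 45 of 62 genes (median -0.0508; adjusted p = 0.061), with Ndufv1 at -0.0901 ± 0.0423 (SE). Glycolysis was lower in 16 of 21 (adjusted p = 0.0876), with Pkm at -0.261 ± 0.0834 and Tpi1 at -0.203 ± 0.0777 (SE; -0.114 after the position correction). The citric acid cycle was lower in 19 of 22 and the sarcomere in 8 of 9 (adjusted p = 0.0876 for each). Ribosomal protein genes were lower in 45 of 67 (adjusted p = 0.0876), with Rpl23 at -0.207 ± 0.0624 and the dim Rps27l at -0.166 ± 0.0681 (SE). Nos3, a dim clone also picked by its P, was lower by -0.342 ± 0.12 (SE) in 5 of 5 number sets, with 6 of 8 endothelial genes lower (adjusted p = 0.139). In settings fixed before the data were seen, 3 lists passed with quantile, 4 with MAD and 4 with loess normalization, 1 without dim clones, 2 with the mean of clones, 1 in the compared mice only and 5 with all clones. In settings chosen afterwards, 4 lists passed after the position correction, 4 without mice 05, 06 and 09 and 6 without mice 05, 09 and 64.

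Males were compared with females at equal age band. The sex-linked genes, which check the labels, differed little: Xist, the X-inactivation RNA, was lower in males by -0.0906 ± 0.0403 (SE), at -0.735 ± 0.148 (SD, n = 19) in males and -0.653 ± 0.0937 (SD, n = 19) in females, and the Y-linked Eif2s3y, a dim clone at percentile 8.61, was higher by 0.104 ± 0.0509 (SE), or 0.0622 ± 0.0896 (SE) after the position correction. Y-linked Uty was at -0.0397 ± 0.0612 (SE), and its sign turned under the position correction. Among X genes that escape inactivation, Kdm5c was at 0.033 ± 0.0699, Kdm6a at 0.0167 ± 0.0581, Ddx3x at 0.0134 ± 0.0571, Eif2s3x at 0.0098 ± 0.0374 and Usp9x at -0.0104 ± 0.0411 (SE), and each of these signs turned under some alternative. Other clones went the other way in 2 of 2 for Ddx3x, 1 of 2 for Kdm6a and 2 of 4 for Usp9x. None passed (adjusted p = 1), so these clones do not settle the sex labels. Wrong labels and clones that fail to measure these genes cannot be told apart here. The sex-linked genes thus gave no check that these arrays detect a known difference, and 0 calls in any comparison may also reflect poor detection.

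Other genes with the smallest P for sex were Maats1 (0.223 ± 0.0666, SE), the decapping gene Dcp1a (0.156 ± 0.052, SE) and Avpi1 (0.15 ± 0.0505, SE), higher in males, and Upf2 (-0.118 ± 0.0403, SE), Asap2 (-0.124 ± 0.043, SE) and Slco6c1 (-0.129 ± 0.0507, SE), lower in males. Each had adjusted p = 1. The Maats1 clone is among the dimmest, at percentile 0.627, and its other clone went the other way, as did 1 of the other 2 clones of Upf2. Slco6c1 is dim, at percentile 9.36. With the position corrected, Avpi1 was at 0.044, Upf2 at -0.0546, Asap2 at -0.0543 and Slco6c1 at -0.0544, and without number set 1 Asap2 was at -0.0824. By limma, 0 clones passed, with 203 at an unadjusted P under 0.05, and the plain linear model called 0. Ribosomal protein genes were higher in males in 45 of 67 (adjusted p = 0.116), and 4 of 4 atrial markers were lower (adjusted p = 0.116). Collagen XIV, Col14a1, was at 0.0959 ± 0.041 and Psma6 of the proteasome at 0.0894 ± 0.0436 (SE; 0.0409 after the position correction). No list passed. With all clones of each gene 1 did, without mice 05, 06 and 09 2 did, and without number set 1 the ribosomal list did (adjusted p = 0.00513).

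The age slope was also compared between the sexes. Bex4 (0.078 ± 0.0254 per 100 days, SE), Med12l (0.0336 ± 0.0122, SE) and Tcaf1 (0.0629 ± 0.0236, SE; a dim clone at percentile 4.55) had more positive slopes in males than in females, and Ddx3x (-0.0335 ± 0.012, SE), Selenop, a selenium transport protein (-0.045 ± 0.017, SE), and Pttg1, securin (-0.0551 ± 0.0216, SE), had more negative ones, each at adjusted p = 1. Selenop was at -0.0247 and Ddx3x at -0.0212 after the position correction, and Bex4 at 0.0484 without number set 1. Glrx, glutaredoxin, was at -0.0455 ± 0.02 (SE), and 23 of 32 antioxidant genes had lower slopes in males (adjusted p = 0.198). In limma 0 clones passed, with 71 at an unadjusted P under 0.05, and the plain linear model called 0. No list passed, though 2 did with the mean of clones and 1 with all clones. The citric acid cycle had lower male slopes in 14 of 22 genes (adjusted p = 0.105), and the ribosomal list, with 44 of 67 lower (adjusted p = 0.128), passed without number set 1 (adjusted p = 0.00036).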

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

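Of 97 groups of 4 to 10 mice tested, 8 held 1 mouse far from the others, where chance would give about 4.85. All 8 outlying values belong to mice of number set 1, and 0 to the other sets. The choice of which lists, genes and bands to test here was made after the data had been seen.

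On array type A, the median correlation with the other arrays was 0.871 for mouse 05 at 169-194 days (next lowest 0.928) and 0.866 for mouse 09 at 476-499 days (next lowest 0.935). On type B it was 0.961 for mouse 01 at 33-44 days (next lowest 0.97). The sarcomere list mean of mouse 14 at 704-743 days was 0.583 (next lowest 0.737), and the citric acid cycle mean of mouse 05 at 169-194 days was 0.133 (next lowest 0.341). Ppip5k1 stood at -1.33 in mouse 01 at 33-44 days (next lowest -1.11). In mouse 06, 6230400D17Rik stood at -3.65 at 169-194 days (next lowest -3). In mouse 14, Poll stood at 1.5 at 704-743 days (next lowest 1.64).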

How the results depend on the processing

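Settings that leave out number set 1 or mice 05, 09 and 64 or 05, 06 and 09, correct for position, or combine log10 of age with set 1 left out or with cyclic loess were chosen after seeing the data, and the cause was not tested except for the calls without set 1. Counts of clones were 0 except as follows. For the slope over all mice they were 3 with array weights, 2 with the number-set block, 3 with sets as a random block, 1 with the mean of clones, 56 without set 1, 164 without set 1 with the block, 26 without set 1 after position correction, 254 with log10 of age without set 1, 422 with the block added, 1 with the 3 by 3 window and block, and 1 with cyclic loess and log10 of age. For 33-44 against 17-19 days they were 9 with array weights and 1 with the 3 by 3 window. For 704-743 against 169-194 days they were 1 after position correction without set 1 and 1 with the 3 by 3 window and block. Leaving out 1 mouse gave 0 to 2 calls for the slope over all mice (2 without mouse 56) and 0 elsewhere.

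Called lists, 1 for the slope over all mice, became 2 with the mean of clones, log10 of age, band ranks and without 17-19 day mice, 3 in males, 0 in females, 0 in each setting without set 1, 3 after position correction with any window, with or without the block, 3 with all clones and 0 with estimated correlation or fry, corrected or not. For the adult slope, 1 became 4 with quantile, MAD or loess normalization, 0 with the block, 3 with the mean of clones, 3 in males, 0 in females, 0 without set 1 with or without block, 6 without mice 05, 09 and 64, 4 without 05, 06 and 09, 5 after position correction, 3 with block, 3 without set 1, 5 with the 3 by 3 window with or without block, 4 and 3 with the 7 by 7 window, 6 with all clones and 0 with estimated correlation or fry, corrected or not. For 33-44 against 17-19 days, 0 became 2 with all clones. For 169-194 against 33-44 days, 0 became 3 without set 1 with or without block, 1 after position correction and 4 without set 1. For 476-499 against 169-194 days, 4 became 2 with the block, 2 in the compared mice only, 0 with estimated correlation or fry, and after position correction 2 with estimated correlation and 1 with fry. For 704-743 against 169-194 days, 0 became 3 with quantile, 4 with MAD and 4 with loess normalization, 1 without dim clones, 2 with the mean of clones, 1 in the compared mice only, 6 without mice 05, 09 and 64, 4 without 05, 06 and 09, 4 after position correction with or without block, 3 without set 1, 5 and 3 with the 3 by 3 window, 4 and 3 with the 7 by 7 window, and 5 with all clones. For sex, 0 became 1 without set 1 with or without block, without mice 05, 09 and 64, and with all clones, and 2 without 05, 06 and 09. For the interaction, 0 became 2 with the mean of clones, 2 without set 1 with or without block, 3 with position correction without set 1, 1 without mice 05, 06 and 09 and 1 with all clones.

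Leaving out 1 mouse, lists ranged from 0 to 3 for the slope over all mice (3 without mouse 41), 0 to 6 for adults (6 without 05), 0 for 33-44 against 17-19 days, 0 to 1 for 169-194 against 33-44 days, 1 to 6 for 476-499 and 0 to 5 for 704-743 against 169-194 days (highest without 05), 0 to 1 for sex and 0 to 4 for the interaction. The adjusted p of oxidative phosphorylation ranged from 0.000189 to 0.0847 for all mice, lost without mouse 01 (0.0847) or 14 (0.0619); from 1.58e-05 to 0.388 in adults, lost without 06 (0.0718), 13 (0.101), 14 (0.289), 33 (0.0898), 45 (0.388), 59 (0.0743) or 60 (0.114); and from 1.29e-05 to 0.18 at 476-499 days, lost without 06 (0.0544), 09 (0.129), 10 (0.0617) or 45 (0.18). The sarcomere list stayed past the threshold throughout (0.000629 to 0.0263), while the citric acid cycle was lost in 16 of 38 fits (0.00129 to 0.39) and glycolysis in 17 (0.00925 to 0.348).

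Direction turned for oxidative phosphorylation over all mice without set 1 with the block (adjusted p = 0.97), with log10 of age (0.842) and both (0.848). Slopes turned for Atp5g3 (-0.00253 and -0.00253) and Atp5b (0.00343 and 0.00442) with the 3 by 3 window without and with block, Pkm with log10 of age without set 1 with block (0.0018), Rps4x after position correction (-0.0014, -0.00125 with block, -0.00247 without set 1) and Rpl38 (0.000135 without set 1). At 33-44 days Serpinh1 turned after correction without set 1 (0.0215) and Emilin1 with the 3 by 3 window (0.0266 and 0.0365). For sex, Uty turned after correction (0.0462, 0.0461 with block, 0.0546 without set 1, 0.0544 and 0.0551 at 3 by 3, 0.0348 and 0.0343 at 7 by 7), Kdm5c without mice 05, 09 and 64 (-0.0415) or 05, 06 and 09 (-0.00617), Kdm6a with array weights (-0.0316), in adults (-0.00354), without set 1 (-0.0319, -0.0176 with block, -0.00198 corrected) and without mice 05, 09 and 64 (-0.0159), Usp9x with the mean of clones (0.0293), Ddx3x with array weights (-0.00798), the mean of clones (-0.0116), without set 1 (-0.0132, -0.00331 with block) and without mice 05, 09 and 64 (-0.045) or 05, 06 and 09 (-0.0154), and Eif2s3x with array weights (-0.00169) and without set 1 (-0.0105, -0.00875 with block). Leaving out 1 mouse, Kdm6a ranged from -0.00765 to 0.0328, Usp9x from -0.0264 to 0.00248, Ddx3x from -0.0146 to 0.0307 and Eif2s3x from -0.00337 to 0.0195. Of 6098 values for 97 named results, each 1 gene in 1 comparison, 6024 kept direction and side of the threshold and 28 passed it, but as none had passed, keeping its side says little. Of 380 values for the 6 called lists, 293 kept both, 84 lost the call and 3 turned.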

Other observations

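Tests chosen after their result had been seen were those on spot position for each pattern below and the test on other red cell genes. The alpha-globin pattern and the fetal heart result were picked out from the values.

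After the position correction, the 8 measured genes listed under the fetal heart programme were lower as a list at 476-499 than at 169-194 days (camera adjusted p = 0.000863, 0.00825 with an estimated correlation, fry adjusted p = 0.00881). On deposited values the list did not pass (adjusted p = 0.0583). Corrected members include Tpm2 at -0.17 ± 0.0546, Acta2, smooth muscle actin, at -0.165 ± 0.0816 and Actn1 at -0.0973 ± 0.0562 (SE). Nppb, the natriuretic peptide gene, was at -0.036 ± 0.0312 (SE) after the correction. The other measured members of the 8 were Casq1, Cnn1, Tpm4 and Myl9. Nppa, Myh7 and Acta1 of the list were not measured, so the result covers only part of the programme. The largest changes were those of Tpm2 and Acta2, and which cells of the heart carry them was not tested. The deposited list mean was 0.62 ± 0.052 (SD, n = 10) at 169-194 days, 0.557 ± 0.0293 (SD, n = 10) at 476-499 days and 0.605 ± 0.0444 (SD, n = 9) at 704-743 days, lower at 476-499 days in 5 of 5 number sets and not lowest in the oldest mice. Picked out from these values, the list gains no separate support from that agreement across sets. The corrected result comes from 1 of the added settings and is a hypothesis only.

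Alpha-globin clones (Hba-a1 and Hba-a2) were lower at 33-44 than at 17-19 days in 16 of 16, by a median of -0.469. Their mean was 1.39 ± 0.201 (SD, n = 4) at 17-19 days, 0.981 ± 0.302 (SD, n = 5) at 33-44 days, 1.05 ± 0.288 (SD, n = 10) at 169-194 days, 1 ± 0.172 (SD, n = 10) at 476-499 days and 0.921 ± 0.212 (SD, n = 9) at 704-743 days. The clones share sequence and count as 1 measurement, and the difference of -0.409 did not pass an exact two-sided permutation test (P = 0.0635 over 126 splits, smallest possible 0.0079). Those splits cross the number sets. After the position correction the difference was -0.293 and the exact permutation P was again 0.0635, so that test cannot tell, and the mean was lower in 2 of 3 number sets holding both bands, which leaves the sets open as a source. The median change of 6 other red cell genes was -0.000758, but Alas2 and Car1 are dim on the array. The clone used for Slc4a1, of middle brightness (percentile 45.8), was at 0.0312 ± 0.111 (SE), which alone settles little. Bpgm (0.0304 ± 0.126), Car2 (-0.0319 ± 0.22) and Fech (-0.0374 ± 0.109, SE) are about as bright as the globin clones and lay near 0. These 3 are also made outside red cells, so fewer blood cells are neither shown nor excluded, and age itself stays untested.

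For oxidative phosphorylation at 476-499 against 169-194 days, the list median of -0.0465 lay at percentile 0 of 10000 random lists matched on brightness. The central 95 percent of those medians ran from -0.0235 to 0.0165, so clones of that brightness at large did not shift as far. The random lists draw unrelated genes and leave out that list members move together. The percentile therefore does not show that the list changed, nor exclude a shared shift of its own clones. Spot position is argued against by camera at the preset correlation alone: the list passed after the position correction (adjusted p = 9.4e-06), but not with an estimated correlation (0.419) or fry (0.421), where it did not pass before the correction either. Neighbouring spots still moved together in part after the correction, so spot position is not excluded for this list or the sarcomere list. The spread between mice stays open, since the list mean per mouse did not pass (difference -0.0369, permutation P = 0.401). For the sarcomere list the percentile was 0.08, with the same limit. Its corrected camera adjusted p was 0.000863 (0.0478 with an estimated correlation, 0.0712 with fry). The list mean per mouse passed (-0.0782, permutation P = 0.0393, and 0.00941 after the position correction). That P is for 1 of 27 lists and is not adjusted for them. The permutations for both lists moved mice across the number sets, so differences between sets are part of the spread they were judged against. A lower mean of the few measured sarcomere genes in middle age may therefore be real, a chance result or drift along the runs of mouse numbers. The splits given below do not exclude chance.

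Leaving out number set 1 gave 56 age slope calls, 54 of them upward. Of these, 12 stayed called among 26 after the position correction, so drift shared by neighbouring spots could account for those lost. The lost calls do not settle it, since the correction also removes real change shared by neighbouring clones. Each of the 56 kept its sign. The limma adjusted p of the lost clones ran from 0.0539 (Ctnnbl1) to 0.961 (an unnamed clone). The median residual SD was 18.5% lower without set 1, which an offset in the level of set 1 would also give. With the number sets in the fit it was 10.3% lower, barely past the 10% set beforehand, so a larger spread of the set 1 arrays may contribute. Other clones of the called genes went the same way in 11 of 21 (exact one-sided binomial P = 0.5), too few to tell whether the genes themselves changed with age. Clones called both ways include Pbk, Unc50, Safb2, Lad1 and Tex19.1.

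Splits of the mice exclude chance for no comparison. As no comparison had a call, clones at an unadjusted P under 0.05 were counted in 100 splits of the mice, the real one included. As many clones were reached in 16 splits for the slope over all mice (1243, highest other 4612), 60 for the adult slope (486, highest other 6172), 31 for 33-44 against 17-19 days (756, highest other 2207), 99 for 169-194 against 33-44 days (69, highest other 3787), 82 for 476-499 against 169-194 days (278, highest other 6196), 58 for 704-743 against 169-194 days (427, highest other 6715), 81 for sex (203, highest other 4177) and 100 for the interaction (71, highest other 6831). As many called lists were reached in 33 splits for the slope over all mice (1 list, highest other 5), 34 for the adult slope (1 list, highest other 5) and 7 for 476-499 against 169-194 days (4 lists, highest other 8). These splits cross the number sets and carry no block. In splits within number sets, fitted with the block, as many clones were reached in 14 of 100 for the slope over all mice (1908, highest other 4502), 19 for the adult slope (1173, highest other 2754), 100 for 169-194 against 33-44 days (107, highest other 4790), 48 for 476-499 against 169-194 days (642, highest other 2955), 28 for 704-743 against 169-194 days (909, highest other 3076), 40 for sex (627, highest other 4477) and 99 for the interaction (178, highest other 4090). For 33-44 against 17-19 days only 8 such splits exist, and the real one was the highest, 1 of 8 (987, highest other 664), too few to tell. As many lists were reached in 47 for the slope over all mice (1 list, highest other 6) and 31 for 476-499 against 169-194 days (2 lists, highest other 7). Between 28 and 50 of the 99 other splits across the sets called at least 1 list in each comparison, so camera at the preset correlation calls lists too readily on these arrays. Splits that reach several times the real number of clones, within number sets too, point to a structure of the samples that age and sex do not carry.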
